A study of Mus musculus with 24 samples.

How the data were processed

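RNA from mouse lung and from the left ventricle of the heart was measured on Affymetrix expression arrays, 24 arrays in 8 groups of 3. The animals were CD-1 mice of 20 weeks, described as male, either wild type or dnCREB. The dnCREB mice carry a dominant negative form of the transcription factor CREB1 in heart muscle cells and are used as a model of cardiac failure. Each mouse received particulate matter (PM, 20 mg/kg, particles of 1.9 µm, tissue taken at 36 h) or phosphate-buffered saline (PBS). The series text speaks of groups of n=3 animals. It does not state whether the lung and the heart of a replicate number came from the same animal.

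The deposited values are log2 expression values per probe set, made by the authors with GCRMA, as the submitters' processing notes name it, with no version given. GCRMA corrects background by probe sequence, normalizes probes between arrays and summarises each probe set. No further normalization was applied. The lowest value per array was 0.52 to 0.56 in lung and -0.22 to -0.20 in heart, and the median was 4.09 to 4.19 in lung and 3.25 to 3.37 in heart, so the tissues appear to have been normalized separately. Differences between tissues were therefore computed only as differences between changes within a tissue. Arrays give no counts, and the number of arrays per group limits the precision.

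Of 45037 probe sets, 34945 matched 1 gene symbol, 932 matched several and 9160 matched none. The last 2 kinds were left out. Each of the 18193 genes was represented by its probe set with the highest mean over all 24 arrays, and 9010 genes had more than 1 probe set to choose from. A gene was tested in a tissue when at least 3 arrays exceeded a log2 value of 4, which left 11600 genes in lung and 9962 in heart. Differences of changes between the tissues were tested over 12328 genes.

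Each tissue was fitted with limma 3.58.1 in R 4.3.3 as 4 group means over 12 arrays, with moderated variances and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p under 0.05. The comparisons were PM against PBS in wild type, in dnCREB and averaged over the genotypes, dnCREB against wild type under PBS and under PM, and the interaction of genotype and PM. The change under PM averaged over the genotypes and the change with dnCREB under PBS were also compared between heart and lung. Changes are given as log2 differences, with standard errors (SE) from limma and standard deviations (SD) over n = 3 arrays. Where a pair of groups was compared and all arrays of 1 of them lay under 4, the fold of a gene called is given against the level of 4 as a lower bound. This was not done for Creb1, for interactions, for tissue differences and for values with an array left out, which are fitted differences and give no bound on a fold. Tables were made with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.

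Gene lists of 3 or more measured members were tested with camera at an inter-gene correlation of 0.01, again with a correlation estimated from the arrays, and with fry. Each p was adjusted over the 31 lists of a comparison. The lists were chemokines and cytokines, acute phase and complement, neutrophil, macrophage and monocyte, lymphocyte, alveolar and airway epithelium, endothelial and smooth muscle, cardiomyocyte and atrial, skeletal muscle, adipocyte, erythroid, mesothelial and lymphoid tissue, aryl hydrocarbon receptor (AhR) and xenobiotic response, oxidative stress and metal response, cell cycle, interferon response, extracellular matrix and fibrosis, coagulation and fibrinolysis, heart failure and hypertrophy, calcium handling and contraction, sodium channels and pumps, potassium and pacemaker channels, gap junction and conduction, adrenergic and renin-angiotensin signalling, CREB and immediate early genes, fatty acid oxidation, oxidative phosphorylation and TCA cycle, glycolysis, circadian clock, glucocorticoid response, and heat shock and unfolded protein response. Counts adjusted over the list alone use only that list's genes in the adjustment.

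The genes named for the main comparisons are the 8 largest rises and the 8 largest falls among genes that passed the test and whose 3 arrays of one group all lay above the 3 of the other. For interactions and tissue differences 5 of each are named. Where no gene passed, the 3 smallest p are given as values. Up to 4 members with the smallest p are named per described list, Creb1 is always given, and predicted genes are skipped. The comparisons, lists, naming rule and the first set of other settings were fixed before the data were examined.

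This first set was all probe sets, no filter, a stricter filter at 6, quantile normalization, arrays centred on their median and all 24 arrays in a joint model. It also held only the groups compared, array weights, a variance trend with robust estimation, and a filter that kept called genes changed at least 1.5-fold. The replicate number as a block and leaving out each array completed it. Added after the values were seen were the sex-chromosome class of the array (Xist above 8, Eif2s3y above 6, or neither) as a covariate, leaving out lung arrays whose skeletal muscle list lay more than 1 log2 unit above the lung mean, that class as a covariate, and leaving out the 2 lung arrays least correlated with the rest. The method was tested on simulated data that kept each gene's spread but drew the genes independently of each other, with 100 genes shifted 2-fold and 100 shifted 4-fold. For PM in wild-type lung it found 48% of the former and 86% of the latter, with 10 false calls. For dnCREB under PBS in heart it found 56% and 89%, with 9 false calls.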

Results

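Expression was measured in lung and left ventricle of wild-type and dnCREB mice given PM or PBS, with 3 arrays in each of the 8 groups and 12 arrays per tissue. Pearson correlations between probe-set values of 2 arrays ranged from 0.951 to 0.996 in lung and from 0.979 to 0.998 in heart, and 0 pairs of arrays were identical.

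Creb1 transcript marked the transgene in the heart. The Creb1 probe set with the largest change, chosen after its values were seen, stood at 2.94 ± 0.30 (SD, n = 3) in wild-type PBS hearts and 2.65 ± 0.19 in wild-type PM hearts, against 10.45 ± 1.43 and 10.39 ± 1.22 in the dnCREB hearts. The difference was 7.51 ± 0.70 (SE) log2 units under PBS (adjusted p = 2.2e-04) and 7.75 under PM (adjusted p = 2.1e-04), fitted values from which no fold is taken, as the wild-type hearts lay under 4. Another rose by 2.81 (adjusted p = 0.0167) and 3.33 (adjusted p = 0.0078). The other Creb1 probe sets gave -0.36, -0.07 and -0.19 under PBS and did not pass, and the last of these fell under PM (-0.82, adjusted p = 0.0202). These p were adjusted over all probe sets tested. In lung, the group means of the first lay between 3.41 and 3.73, so the genotype of the lung samples cannot be checked with it.

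The sex-chromosome genes did not follow the single sex named in the labels. Xist, the RNA that silences an X chromosome in female cells, was high in 13 arrays, the Y-linked gene Eif2s3y in 9, and neither in 2. All 6 wild-type hearts had high Xist, all 3 dnCREB PBS hearts and 2 of the dnCREB PM hearts had high Eif2s3y, and dnCREB PM replicate 3 had high Xist. In lung, the 3 wild-type PBS arrays had high Eif2s3y, wild-type PM replicates 1 and 3 and all 3 dnCREB PM arrays had high Xist, and dnCREB PBS held 1 array with high Xist and 2 with neither. Lung wild-type PM replicate 2 had Eif2s3y at 8.43 and Kdm5d at 6.81 but Uty, also on the Y chromosome, at 3.39. Skeletal muscle genes were high in 5 lung arrays, which were wild-type PM replicates 1 and 2, dnCREB PBS replicates 1 and 3 and dnCREB PM replicate 3. The lung arrays least correlated with the others were wild-type PBS replicate 1 (median r of 0.924) and wild-type PM replicate 2 (0.929).

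**Figure D1:**
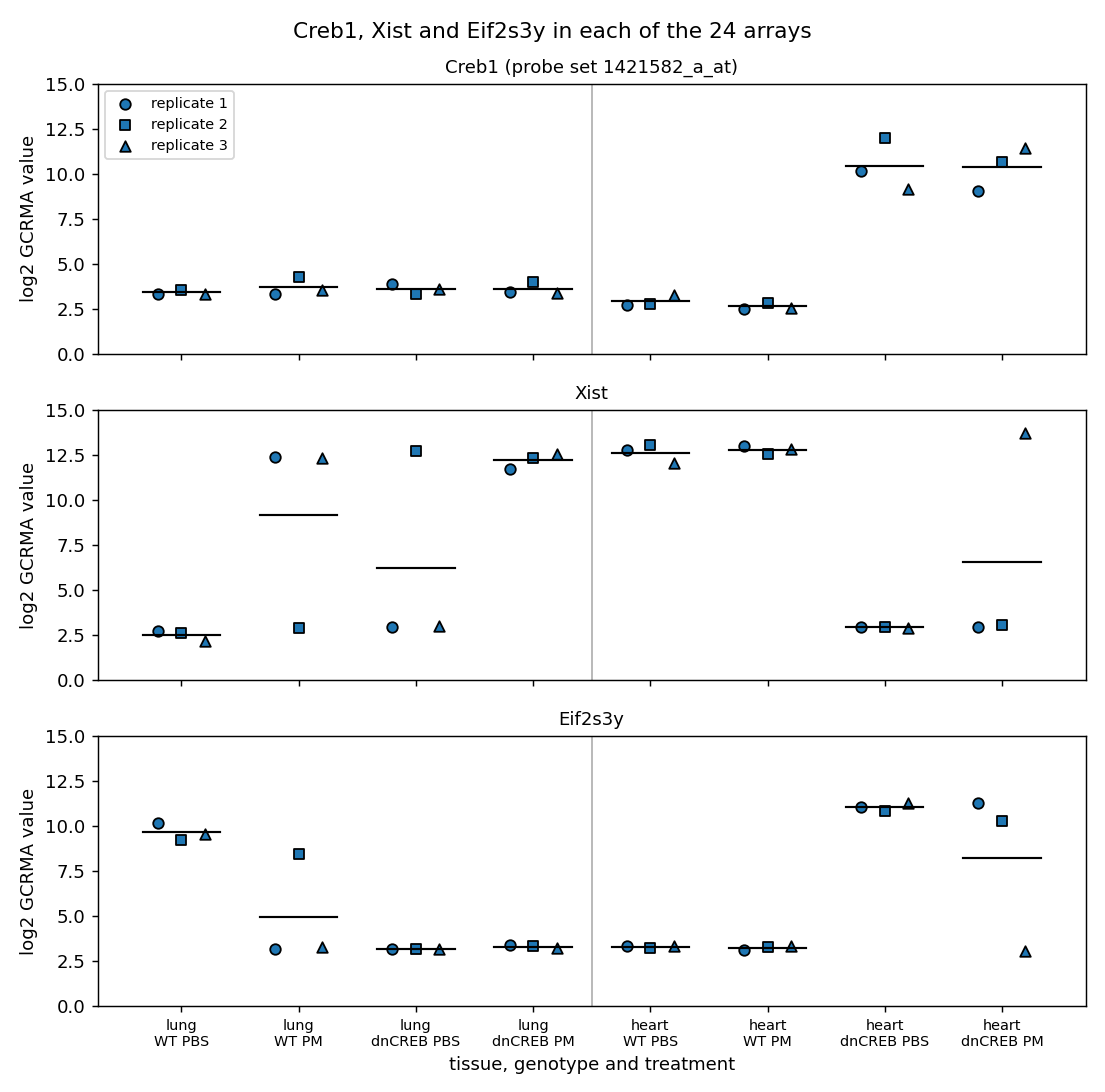
Log2 values of the Creb1 probe set with the largest change, Xist and Eif2s3y in each of the 24 arrays by group, with a line at the group mean. Creb1 averaged 10.45 in dnCREB PBS hearts and 2.94 in wild-type PBS hearts, and Xist was high in 13 arrays.

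The left ventricle of dnCREB mice under PBS was compared with that of wild-type mice to see how the failing heart model differs before any particle exposure. Comp, a cartilage and tendon matrix glycoprotein, went from 4.18 ± 0.01 to 11.25 ± 0.56 (SD, n = 3), a log2 change of 7.07 ± 0.30 (SE, adjusted p = 9.2e-07). Ltbp2, a protein of elastic microfibrils, was at least 40.3-fold higher (adjusted p = 4.3e-06), Ecrg4, a secreted peptide precursor, at least 78.9-fold (adjusted p = 0.0028), Ccn5, a matricellular protein, at least 35.5-fold (adjusted p = 4.0e-06), and Sfrp2, a secreted Wnt modulator, at least 25.2-fold (adjusted p = 0.0132). Kcnj14, an inward rectifier potassium channel, was at least 40.4-fold higher (adjusted p = 0.0050). Ces1d, a lipid hydrolase, fell from 12.40 ± 0.23 to 6.06 ± 1.48 (SD), a change of -6.35 ± 0.87 (SE, adjusted p = 0.0011). Kcnj3, a channel subunit of the acetylcholine-activated potassium current, changed by -4.33 ± 0.60 (adjusted p = 0.0011), and the water channel Aqp4 was at least 6.82-fold lower (adjusted p = 1.4e-06). Cep128 (-4.68 ± 0.14) and Cabcoco1 (-4.56 ± 0.34) also fell, Trim12c was at least 7.82-fold lower and the kinetochore gene Cenpf at least 8.33-fold, with an SD of 2.88 in wild type. Eif2s3y (at least 133-fold higher), Uty (at least 28.7-fold higher) and Xist (at least 395-fold lower) were among the largest changes, as the sex-chromosome classes of these arrays differ completely between the genotypes.

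In all, 1311 genes were higher and 558 lower, a total of 1869 of 9962, with 928 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 3299 genes, against 498 by chance, and 4255 genes had groups that did not overlap, against a chance share of 10%. The median of all genes was 0.09, and centring the arrays moved it by -0.22 to -0.13, which turned the split to 918 higher and 1187 lower, while quantile normalization gave 1084 and 851. List medians for this comparison are therefore given relative to the median of all genes. With the sex-chromosome class as a covariate, 337 genes were called, 304 of them shared, an estimate that rests on dnCREB PM replicate 3 alone. Leaving out dnCREB PBS replicate 3 gave 1091 genes, and leaving out wild-type PBS replicate 3 gave 1182.

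Of 31 measured extracellular matrix and fibrosis genes, 21 rose and none fell (26 and 0 adjusted over the list alone; 15 with the sex class as a covariate), with a median of 1.68. The median was 2.93 with the sex class. Besides Comp and Ltbp2, the metalloproteinase inhibitor Timp1 was at least 17.4-fold higher and the proteoglycan Vcan changed by 3.98. The camera test gave an adjusted p = 5.8e-12, and adjusted p = 0.1657 with an estimated correlation. In the heart failure and hypertrophy list, 13 of 19 members rose and 1 fell (13 and 1 adjusted over the list alone; 4 and 0 with the sex class), with a median of 1.49. The median was 2.08 with the sex class. Examples are the matrix protein Cilp (5.22), the stretch-responsive Fhl1 (1.57) and Ankrd1 (1.01), and the calcineurin inhibitor Rcan1 (2.64). The natriuretic peptide Nppb (2.40), the slow myosin Myh7 (3.17) and skeletal actin Acta1 (1.46), chosen after their values were seen, also rose. The camera test gave an adjusted p = 2e-05, and adjusted p = 0.1313 with an estimated correlation.

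Potassium and pacemaker channels fell in 9 of 19 members and rose in none (10 lower adjusted over the list alone; 2 with the sex class), with a median of -0.72. The median was -0.77 with the sex class. Kcnj14, the potassium channel named above for its large rise, is not a measured member of this list. Kcnd2, a pore subunit of the transient outward current, changed by -1.65, the ATP-sensitive channel subunit Abcc9 by -0.90 and Kcnj5, the partner of Kcnj3, by -1.20. This list was called by camera (adjusted p = 2.8e-08), with an estimated correlation (adjusted p = 0.0176) and by fry (adjusted p = 4.1e-05). In the calcium handling and contraction list, 4 of 22 members fell and 1 rose (5 and 2 adjusted over the list alone; 0 with the sex class), while 8 fell and 0 rose with centred arrays and 6 fell and 1 rose with quantile normalization. The calcium channel Cacna1c changed by -0.78, the release channel Ryr2 by -0.96, the store protein Hrc by -1.24 and Asph by 0.60. Its camera result (adjusted p = 0.0262) was not kept, with adjusted p = 0.6284 with an estimated correlation. Adrenergic and renin-angiotensin genes fell in 5 of 14 members and rose in 1 (5 and 1 adjusted over the list alone; 1 and 1 with the sex class). The converting enzyme Ace rose by 2.52, while the phosphodiesterase Pde3a (-1.94), the angiotensin receptor Agtr1a (-1.5) and the adenylyl cyclase Adcy6 (-0.99) fell (camera adjusted p = 0.1239).

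In fatty acid oxidation, 15 of 24 members fell and 1 rose (16 and 1 adjusted over the list alone; 3 and 0 with the sex class), with a median of -0.85. The median was -1.06 with the sex class. The hydratase Echs1 changed by -1.0, the lipid-sensing regulator Ppara by -1.37, the reductase Decr1 by -1.29 and the dehydrogenase Acadvl by -0.87. The camera test gave an adjusted p = 2.7e-10, and adjusted p = 0.2916 with an estimated correlation. In oxidative phosphorylation and the TCA cycle, 17 of 33 members fell and none rose (27 lower adjusted over the list alone; 1 with the sex class; 29 with centred arrays and 14 with quantile normalization), with a median of -0.49. The median was -0.40 with the sex class. Examples are the succinate dehydrogenase subunit Sdha (-0.78), the complex I subunit Ndufs1 (-0.62), Suclg1 (-0.73) and the complex III subunit Uqcrc1 (-0.52). The camera test gave an adjusted p = 1e-13, and adjusted p = 0.3567 with an estimated correlation.

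**Figure D2:**
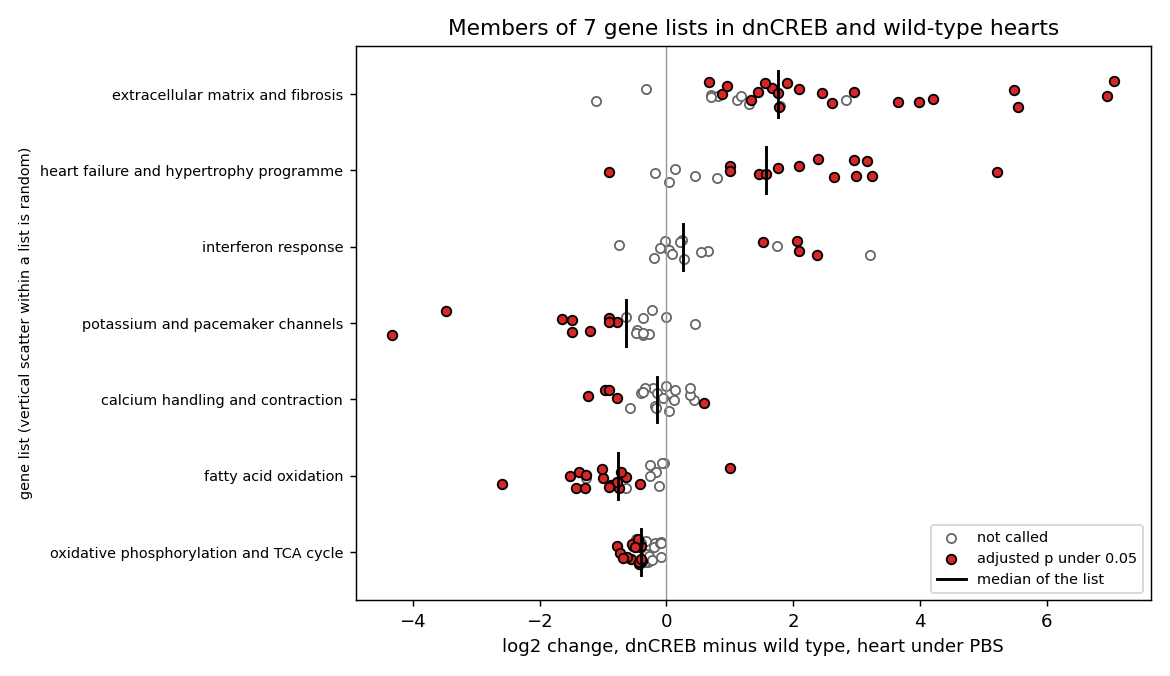
Log2 change of each measured member of 7 gene lists, dnCREB minus wild type in heart under PBS, with filled points for an adjusted p under 0.05 and a bar at the list median. In the matrix list 21 of 31 members rose, and in oxidative phosphorylation and the TCA cycle 17 of 33 fell.

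Smaller groups in the dnCREB heart moved in part, none of them with a camera adjusted p under 0.05. Coagulation and fibrinolysis rose in 5 of 12 members (5 adjusted over the list alone; 2 with the sex class), among them the plasminogen activator Plat (1.66), Fgl2 (2.17), the protein C receptor Procr (2.47) and protein S, Pros1 (0.81). Interferon response genes rose in 4 of 18 (4 adjusted over the list alone; 0 with the sex class), namely Ifit2 (2.38), Oasl2 (2.10), the RNA sensor Ifih1 (1.53) and Ifi27l2a (2.07). Among CREB and immediate early genes, the survival factor Bcl2 (2.89) and the CREB relative Crem (1.55) rose, while the phosphatase Dusp1 (-1.25) and the mitochondrial coactivator Ppargc1a (-2.86) fell, out of 21 members (3 higher and 2 lower adjusted over the list alone; 1 and 3 with the sex class; 2 and 4 with centred arrays). In acute phase and complement, Lbp (2.64) and Cp (1.66) rose of 11 members (3 adjusted over the list alone; 1 with the sex class), with 1 called under centred arrays or quantile normalization, where Cp lost its call, and Ptx3 stood at 1.65 (adjusted p = 0.0525). Of sodium channels and pumps, the pump regulator Fxyd5 (2.66), Scn7a (1.5) and the pump subunit Atp1b1 (0.75) rose of 7 members (3 higher and 1 lower adjusted over the list alone; 0 with the sex class; 2 higher and 1 lower with centred arrays, where Atp1b1 lost its call). Gap junction and conduction genes moved both ways, with connexin Gjc1 (1.01) and Irx3 (0.95) higher and connexin Gja3 (-1.22) lower of 10 members (3 and 1 adjusted over the list alone; 0 and 1 with the sex class), and Irx3 lost its call under both scalings. With the sex class the medians of these 6 lists were 0.60, 0.58, -0.88, 1.21, 0.79 and 0.01, against 0.62, 0.17, -0.53, 1.57, 0.35 and -0.12 without it.

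The same genotype comparison under PM asked whether the difference holds in exposed animals. It called 1132 genes higher and 910 lower, a total of 2042 (3387 at an unadjusted p under 0.05; 975 at least 2-fold), and centred arrays gave 1013 and 1353. Of the genes called under PBS, 817 higher and 440 lower genes were shared, against 149 and 51 for independent calls, and 0 were called in opposite directions. Changes under PBS and PM correlated across genes (r = 0.87), and genes are not independent replicates. Comp (6.28), Ltbp2 (at least 28.9-fold), Cilp (5.91) and Fhl1 (1.55) were higher again. The matrix list rose in 21 of 31 members (22 adjusted over the list alone; adjusted p = 0.1068 with an estimated correlation) and the heart failure list in 11 of 19, with 2 lower (13 and 2 adjusted over the list alone; adjusted p = 0.1068 with an estimated correlation). Oxidative phosphorylation and TCA genes fell in 23 of 33 (32 adjusted over the list alone; 7 with the sex class; adjusted p = 0.3408 with an estimated correlation), as with Sdha (-0.87) and Ndufa5 (-0.73). Fatty acid oxidation fell in 15 of 24 and rose in 1 (17 and 1 adjusted over the list alone; 8 and 0 with the sex class; adjusted p = 0.3408 with an estimated correlation), and potassium channels fell in 8 of 19 and rose in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.0596 with an estimated correlation), with Kcnd2 at -2.35 and Kcnj3 at -5.53. With the sex class the median of oxidative phosphorylation went from -0.47 to -0.44 and that of fatty acid oxidation from -0.80 to -0.91.

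Macrophage and complement genes were higher in exposed dnCREB hearts than in exposed wild-type hearts. Under PBS the medians relative to all genes were 0.78 for macrophage markers (1 of 14 called) and 1.57 for acute phase and complement (2 of 11 called). The interaction called 0 genes, so the difference was not shown to depend on exposure. Macrophage and monocyte markers rose in 10 of 14 members (13 adjusted over the list alone; 4 with the sex class as a covariate), with a median of 1.78 relative to all genes. The median was 1.88 with the sex class. The growth factor receptor Csf1r changed by 1.81, the protease Ctss by 1.78, the lysozyme Lyz1 by 1.34, and the endotoxin receptor Cd14 was at least 5.90-fold higher. The camera test gave an adjusted p = 3.5e-06, and adjusted p = 0.3408 with an estimated correlation. Acute phase and complement rose in 6 of 11 members (6 higher and 1 lower adjusted over the list alone; 1 with the sex class, with medians of 1.82 without and 2.12 with it), with the acute phase inhibitor Serpina3n at 5.16, Lbp at 3.40 and the complement subunits C1qb at 2.07 and C1qc at 2.60. Its camera adjusted p was 0.0085, and adjusted p = 0.5430 with an estimated correlation. C1qc lost its call without dnCREB PM replicate 3, which gave 2.52, and without wild-type PM replicate 3, which gave 2.06. In this comparison, values with the sex class rest on dnCREB PM replicate 3 alone, so no count over all genes is given for that setting. With only the groups compared, 1168 genes were called.

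In the heart, PM against PBS asked how particle exposure acts on the ventricle. In wild type the water channel Aqp4 fell from 6.77 to 4.83, a change of -1.94 ± 0.20 (SE, adjusted p = 0.0147), the single gene limma called (146 at an unadjusted p under 0.05, 498 by chance; 542 genes with groups that did not overlap, where chance gives 10%). The call was lost without wild-type PBS replicate 1 (-1.81) or 2 (-1.79) and without wild-type PM replicate 1 (-1.90) or 3 (-1.96), and 3 genes were called without wild-type PM replicate 2. In dnCREB hearts limma called 0 genes (490 at an unadjusted p under 0.05), and the smallest p belonged to Shld1 (1.33, adjusted p = 0.3545), Tmem62 (-0.98, adjusted p = 0.3545) and Dapp1 (-1.07, adjusted p = 0.4851). Averaged over the genotypes limma called 0 genes (185 at an unadjusted p under 0.05; smallest adjusted p = 0.4891). The interaction had 0 calls by limma (361 at an unadjusted p under 0.05), with Aqp4 at 2.02 (adjusted p = 0.2377), Shld1 at 1.63 (adjusted p = 0.6767) and Dapp1 at -1.22 (adjusted p = 0.9801). Without dnCREB PM replicate 2 or 3, or dnCREB PBS replicate 1, 5, 4 and 1 genes were called in dnCREB hearts. Averaged, 2 were called without dnCREB PM replicate 3 and 1 without wild-type PBS replicate 3, and for the interaction 1, 3 and 1 without dnCREB PM replicate 2, dnCREB PM replicate 3 and wild-type PBS replicate 3. On simulated data the same tests found 67% of genes shifted 2-fold in wild type and 66% in dnCREB. Those genes were drawn independently and many were shifted at once, so these shares may not hold where only a few genes change.

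The macrophage and glucocorticoid lists, among others, had medians of opposite sign with PM in wild-type and dnCREB hearts. List medians in this paragraph are not relative to all genes. limma called 0 members of the macrophage and glucocorticoid lists, and 0 adjusted over the list alone (146 and 490 genes at an unadjusted p under 0.05). In wild type the macrophage list had a median of -0.47 (camera adjusted p = 1.3e-08; adjusted p = 0.559 with an estimated correlation), CREB and immediate early genes -0.38 (4.4e-06; adjusted p = 0.559 with an estimated correlation) and glucocorticoid response -0.40 (5.8e-05; adjusted p = 0.679 with an estimated correlation). In dnCREB the glucocorticoid list stood at 0.46 (camera adjusted p = 7.3e-04; adjusted p = 0.6732 with an estimated correlation) and the macrophage list at 0.30 (0.0154; adjusted p = 0.6732 with an estimated correlation). The difference itself had a median of 0.87 for macrophage markers (camera adjusted p = 6.3e-08) and 0.74 for glucocorticoid response (1.3e-07), both with adjusted p = 0.3879 with an estimated correlation. CREB and immediate early genes (0.52) and chemokines (0.20) had a camera adjusted p = 0.0171 for the difference, and adjusted p = 0.4175 with an estimated correlation. With the sex class these medians of the difference were 0.70 and 0.39, and those of the macrophage and glucocorticoid lists 0.89 and 1.04. The median of the CREB list in dnCREB was -0.14, and 0.19 with the sex class. Among the exposed dnCREB hearts, replicate 3 differed from the others in its sex-chromosome class.

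In wild-type lung, PM raised and lowered single genes. Fcgr1, the high-affinity IgG receptor of macrophages, went from 5.03 ± 0.51 to 8.31 ± 1.01 (SD, n = 3), a log2 change of 3.28 ± 0.49 (SE, adjusted p = 0.0150). The scavenger receptor Marco was at least 3.95-fold higher (adjusted p = 0.0225), the macrophage elastase Mmp12 rose by 3.07 ± 0.69 (adjusted p = 0.0460) and the immunoglobulin chain Ighg3 by 4.27 ± 0.81 (adjusted p = 0.0275). Esm1, secreted by activated endothelium, rose by 3.21 ± 0.58 (adjusted p = 0.0239), the actin bundler Fscn1 by 2.90 ± 0.40 (adjusted p = 0.0123) and the matrix glycoprotein Tnc by 2.68 ± 0.55 (adjusted p = 0.0335). Olfm2 was at least 2.70-fold higher (adjusted p = 0.0117). Sema3c, a guidance cue of lung epithelium and vessels, fell from 13.71 to 10.51 (-3.21 ± 0.45, adjusted p = 0.0123), and the lung mesenchyme RNA Fendrr fell from 11.10 to 9.27 (-1.83 ± 0.27, adjusted p = 0.0150). Calcb, a neuropeptide, was at least 2.54-fold lower, and the cilia motor gene Dnah12 (-2.00), the sodium channel Scn7a (-1.82) and Zfp386 (-1.82) also fell. Uty (at least 11.9-fold) and Eif2s3y (-4.71) fell, where all 3 PBS arrays and 1 of the 3 PM arrays had high Eif2s3y.

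limma called 227 genes higher and 50 lower with PM in wild-type lung, 277 of 11600, with 224 changed at least 2-fold. At an unadjusted p under 0.05 there were 3051 genes (580 by chance), and 3072 had groups that did not overlap (chance share 10%). The median of all genes was 0.11 and moved by -0.14 with centred arrays, which split the calls 149 to 108, so list medians are given relative to all genes. Leaving out the 5 arrays with high skeletal muscle genes left wild-type PM replicate 3 as the only exposed wild-type array, so no count is given for that setting. With the muscle class as a covariate 11 genes were called, and without the 2 least correlated arrays 27. With the sex class as a covariate the change rests on wild-type PM replicate 2 alone, so no count is given for that setting. It was the only exposed wild-type lung with high Eif2s3y, as in all 3 PBS arrays. The count was 147 without wild-type PBS replicate 1, 34 without wild-type PBS replicate 2, 622 without wild-type PM replicate 1 and 50 without wild-type PM replicate 2. Of the 16 genes named above, 11 lost their call without at least 1 of the 6 arrays, while Sema3c, Fscn1 and Olfm2 kept it without each. Calcb and Uty were not tested without a wild-type PBS array, as fewer than 3 arrays then exceeded the level of 4.

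Interferon response genes rose in 10 of 23 members (17 adjusted over the list alone, 0 with the muscle class as a covariate, 5 with centred arrays), with a median of 1.25. The median was 1.15 with the muscle class. Examples are the peptide transporter Tap1 (1.76), the interferon-induced GTPases Irgm1 (1.36) and Igtp (1.71) and the regulator Irf7 (2.53), with a camera adjusted p = 2e-08, and adjusted p = 0.639 with an estimated correlation. Macrophage and monocyte markers rose in 3 of 22 members, Fcgr1, Marco and Mmp12 (12 adjusted over the list alone, 0 with the muscle class, 2 with centred arrays). Their median was 1.01, and 0.89 with the muscle class, with a camera adjusted p = 1.6e-06, and adjusted p = 0.639 with an estimated correlation. The protease Ctss stood at 1.46 (adjusted p = 0.0508). Lymphocyte markers rose in 4 of 20 members (12 adjusted over the list alone, 1 with the muscle class), namely Nkg7 (2.09), the chemokine Ccl5 (2.02), granzyme Gzmb (1.54) and perforin Prf1 (1.90). Their median was 0.98, and 0.87 with the muscle class, the camera adjusted p = 1.6e-06, and adjusted p = 0.2437 with an estimated correlation. Extracellular matrix genes rose in 3 of 31 members (21 adjusted over the list alone, 0 with the muscle class, 2 with centred arrays), with Mmp2 at 1.47 and Ltbp2 at 1.68 besides Tnc. Their median was 0.83, also with the sex class, and 0.98 with the muscle class, the camera adjusted p = 1.6e-06, and adjusted p = 0.6496 with an estimated correlation.

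Complement and acute phase genes rose in 2 of 18 members, C1qb (2.38) and C1qc (2.65) (8 higher and 2 lower adjusted over the list alone), with Cfb at 1.76 (adjusted p = 0.0501), Saa3 at 4.51 (adjusted p = 0.0519) and a camera adjusted p = 0.0641. Neutrophil markers had 0 of 16 members called by limma (2 adjusted over the list alone), a median of 0.92, a camera adjusted p = 0.0158, and adjusted p = 0.965 with an estimated correlation. Chemokines and cytokines had 0 of 16 called (1 adjusted over the list alone), with Cxcl16 at 1.02 and Ccl9 at 1.25. Skeletal muscle genes had a median of 4.89 with 0 of 10 called, a camera adjusted p = 0.037, and adjusted p = 0.965 with an estimated correlation. Of the PM arrays 2 of 3 were high in them, and no PBS array was. The remaining one, wild-type PM replicate 3, scored -0.96, still above the wild-type PBS arrays (-2.81 to -2.67). All exposed wild-type lungs thus lay above the PBS lungs in muscle genes, and the muscle class as a covariate counts replicate 3 as not high. Glycolysis had 0 of 18 called (3 higher and 1 lower adjusted over the list alone), a camera adjusted p = 0.0391, and adjusted p = 0.965 with an estimated correlation. The AhR and xenobiotic list had a median of -0.55 with 0 of 7 called, and its marker Cyp1a1 stood at 1.39. Oxidative stress genes had 0 of 18 called, with Hmox1 at 1.24. Alveolar and airway epithelium had 0 of 25 called (1 adjusted over the list alone), with Scgb3a1 at 2.22 (adjusted p = 0.0508).

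**Figure D3:**
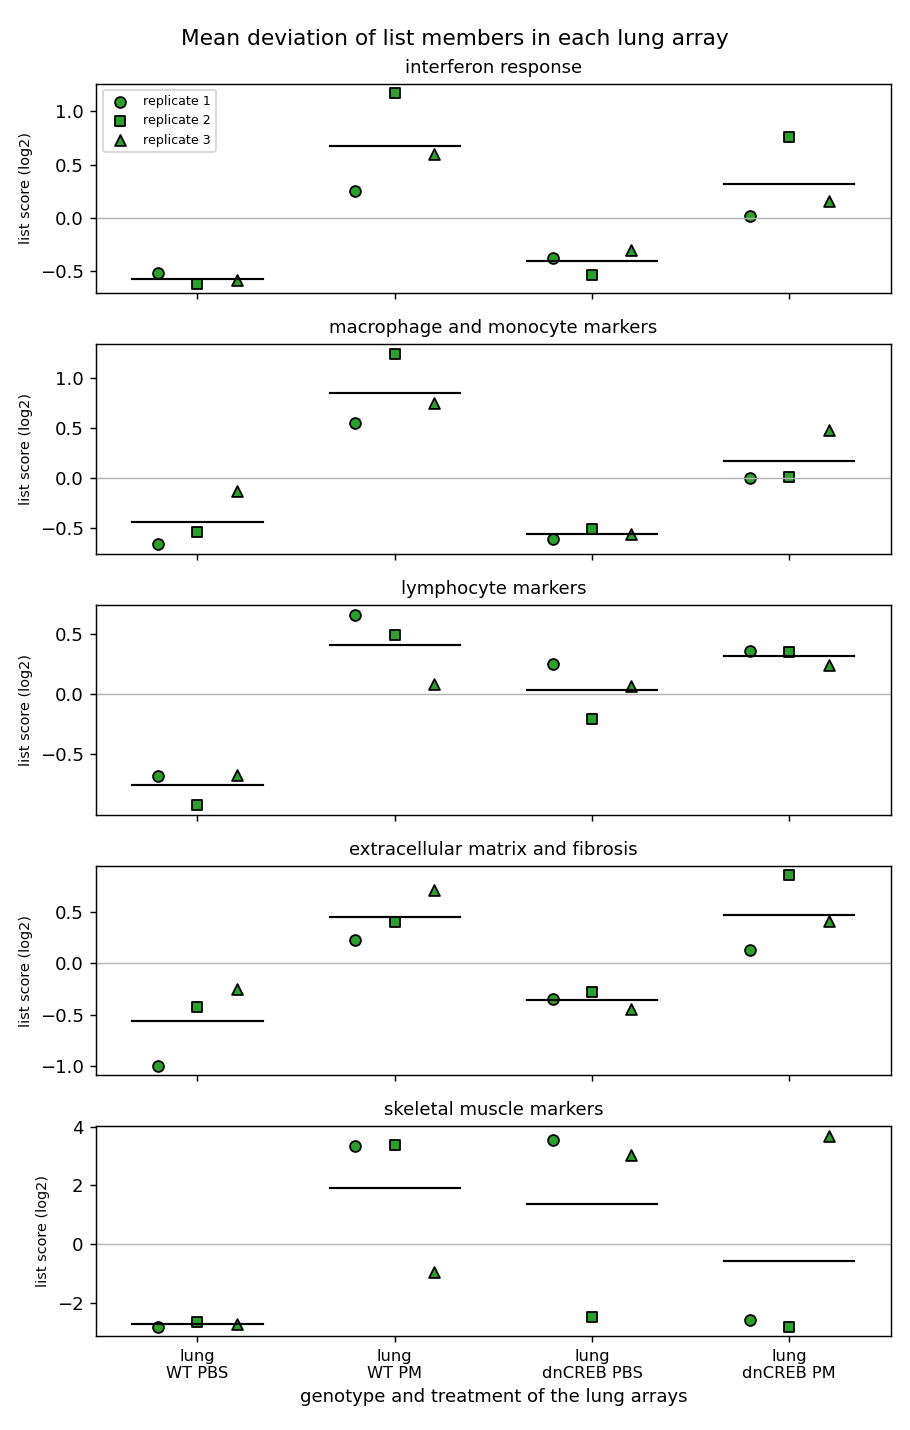
Mean score (log2, relative to the lung mean) of 5 gene lists in each of the 12 lung arrays by group, with a line at the group mean. The mean of the interferon, macrophage and lymphocyte scores was at least 0.13 in the PM arrays and at most -0.25 in the PBS arrays.

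Averaged over the genotypes, PM in lung called 627 genes higher and 157 lower, 784 in all (3226 at an unadjusted p under 0.05; 259 at least 2-fold; 377 and 316 with centred arrays). Interferon genes rose in 12 of 23 members (17 adjusted over the list alone; 11 with the muscle class), with Tap1 at 1.5, Igtp at 1.48 and Irf7 at 2.02. Macrophage markers rose in 8 of 22 (16 adjusted over the list alone; 6 with the muscle class), with Fcgr1 at 2.36, Mmp12 at 3.02 and the IgG receptor Fcgr3 at 0.98. Matrix genes rose in 10 of 31 (21 adjusted over the list alone; 10 with the muscle class), with Ltbp2 at 1.83, Mmp2 at 1.14, Tnc at 2.28 and the membrane metalloproteinase Mmp14 at 1.40. Lymphocyte markers rose in 6 of 20 (8 adjusted over the list alone; 6 with the muscle class), with Nkg7 at 1.69 and Gzmb at 1.51. All 4 lists had adjusted p = 0.5047 with an estimated correlation. Complement and acute phase rose in 7 of 18 (10 higher and 1 lower adjusted over the list alone; 5 with the muscle class; adjusted p = 0.8202 with an estimated correlation), with C1qb at 2.09 and Saa3 at 3.66. Chemokines rose in 3 of 16 (5 adjusted over the list alone; 2 with the muscle class; adjusted p = 0.8202 with an estimated correlation), namely Ccl9 (1.32), Cxcl16 (0.90) and Cxcl10 (1.17). Leaving out the 5 arrays with high muscle genes left wild-type PM replicate 3 and dnCREB PBS replicate 2 as the only arrays of their groups, so no count is given for that setting. The count was 1324, 466 and 509 without wild-type PM replicates 1, 2 and 3 and 285 without wild-type PBS replicate 2. It was 171 and 379 without dnCREB PM replicates 2 and 3, and 225, 340 and 155 without dnCREB PBS replicates 1, 2 and 3.

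In dnCREB lung, PM raised Cpxm2, a carboxypeptidase-like secreted protein, at least 2.61-fold (adjusted p = 0.0416), the single gene called (1127 at an unadjusted p under 0.05, 580 by chance; 3371 with groups that did not overlap, chance share 10%). Without any of 5 of the 6 arrays compared, dnCREB PBS replicates 1 (1.73), 2 (1.79) and 3 (1.92) and dnCREB PM replicates 1 (1.77) and 2 (1.68), this call was lost. Unlike those for wild-type lung, the list medians of the main fit given here are not relative to the median of all genes, which was 0.07. Interferon genes had a median of 0.76 with 0 of 23 called (8 higher and 1 lower adjusted over the list alone), a camera adjusted p = 5.4e-06, and adjusted p = 0.6021 with an estimated correlation. Tap1 stood at 1.24 (adjusted p = 0.2208), Igtp at 1.26 and Oas1a at 1.95. Matrix genes had a median of 0.54 with 0 of 31 called (10 adjusted over the list alone), a camera adjusted p = 5.4e-06, and adjusted p = 0.6021 with an estimated correlation, with Timp1 at 3.16 and Eln at 3.01. Macrophage markers had a median of 0.57, a camera adjusted p = 6.4e-04, and adjusted p = 0.6021 with an estimated correlation, with Mmp12 at 2.97. Lymphocyte markers had a median of 0.34 with 0 of 20 called (2 adjusted over the list alone) and 12 of 20 above 0. Their camera adjusted p was 0.3132, and adjusted p = 0.7689 with an estimated correlation. CREB and immediate early genes had a median of -0.37, a camera adjusted p = 0.0015, and adjusted p = 0.6021 with an estimated correlation, with Jun at -0.99 and Dusp1 at -0.94. The circadian clock list had a median of -0.74 with 0 of 16 called (0 adjusted over the list alone), a camera adjusted p = 0.0246, and adjusted p = 0.6054 with an estimated correlation. Its median was -0.34 with the sex class. Skeletal muscle genes had a median of -2.30 here, as 2 of the PBS arrays and 1 of the PM arrays were high in them.

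Of the genes raised by PM in wild-type lung, 219 of 227 (96.5%) had the same sign in dnCREB lung, with medians of 1.40 and 0.65, and of those lowered, 37 of 50 (74%), with medians of -1.26 and -0.22. The interaction of genotype and PM called Uty (4.81 ± 0.42, SE, adjusted p = 0.0022) and no other gene (606 at an unadjusted p under 0.05). The Y-linked Uty averaged 7.58 in wild-type PBS lungs and 2.84, 2.54 and 2.61 in wild-type PM, dnCREB PBS and dnCREB PM lungs. Wild-type PBS was the only lung group whose arrays all had high Eif2s3y, so a difference in the PM response between the genotypes was not shown for any gene. Without any wild-type PBS array Uty fell under the level filter and limma called 0 genes, and 3 were called without wild-type PM replicate 2. The list medians of the interaction, not taken relative to all genes, were -0.90 for lymphocyte markers (camera adjusted p = 2.4e-06, and adjusted p = 0.2245 with an estimated correlation). For interferon response the median was -0.52 (camera adjusted p = 5.2e-04, and adjusted p = 0.8537 with an estimated correlation).

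The dnCREB lung was compared with wild-type lung to see whether a transgene made for heart muscle is accompanied by lung changes. Under PBS all 3 wild-type arrays had high Eif2s3y and 0 of the dnCREB arrays did, while skeletal muscle genes were high in 0 wild-type and 2 dnCREB arrays. Genotype cannot be told apart from these classes in the PBS values that follow. List medians in this paragraph are not relative to all genes. Under PBS, Angpt2, an endothelial ligand that destabilises vessels, rose by 1.22 ± 0.16 (SE, adjusted p = 0.0415), and Tdgf1, a developmental co-receptor, was at least 1.88-fold lower (adjusted p = 0.0056), besides Uty (at least 11.9-fold lower, adjusted p = 3.5e-05), for 3 genes in all (629 at an unadjusted p under 0.05, 580 by chance; 1606 with groups that did not overlap, chance share 10%). Lymphocyte markers had a median of 0.73 with 0 of 20 called by limma (2 adjusted over the list alone), called by camera (adjusted p = 3.3e-11), with an estimated correlation (adjusted p = 0.0408) and by fry (adjusted p = 0.0379). The T cell receptor partner Cd5 stood at 2.09 (adjusted p = 0.2167), Ccl5 at 1.2, Prf1 at 1.16 and Nkg7 at 0.80. Skeletal muscle genes (4.54) and adipocyte genes (1.55) were higher in the same arrays by camera, both with adjusted p = 0.6286 with an estimated correlation. Under PM limma called 0 genes (461 at an unadjusted p under 0.05; smallest adjusted p = 0.9010), and macrophage markers had a median of -0.67 (camera adjusted p = 5.4e-08; adjusted p = 0.9129 with an estimated correlation). Angpt2 lost its call without any wild-type PBS or dnCREB PBS array (1.16 to 1.32), and Tdgf1 without dnCREB PBS replicate 1 or 3, each of which gave -1.82. Without a wild-type PBS array, Tdgf1 and Uty fell under the level filter and were not tested, which left 0 calls without replicate 1 or 2 and 5 without replicate 3.

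The PM response averaged over the genotypes differed between heart and lung in 204 genes (35 higher and 169 lower in heart relative to lung; 2079 at an unadjusted p under 0.05; 57 and 99 with centred arrays). Of these, 113 passed the level filter in lung only, so their values restate the change in lung, as for Saa3 (-3.58) and Mmp12 (-3.04). Among the 91 that passed it in both tissues, Esm1 differed by -2.91, Timp1 by -2.83 and the anaphylatoxin receptor C3ar1 by -2.59, and Sema3c by 2.02. Interferon genes were lower in heart relative to lung in 4 of 23 members (16 adjusted over the list alone; adjusted p = 0.2789 with an estimated correlation), and 2 of these 4 passed the filter in both tissues. Of 21 lymphocyte markers 3 did, with 0 of them called, so that list was not compared. The dnCREB effect under PBS differed in 987 genes (719 higher and 268 lower in heart relative to lung; 2659 at an unadjusted p under 0.05; 445 and 581 with centred arrays), of which 870 passed the level filter in both tissues, with Ltbp2 (7.66) and Timp1 (7.05) the largest rises besides the Y-linked genes and Xist (-13.41) and Car3 (-7.32) the largest falls. Matrix genes were higher in heart relative to lung in 12 of 33 members (14 adjusted over the list alone; adjusted p = 0.2188 with an estimated correlation). Fatty acid oxidation was lower in 11 of 24 (15 lower and 1 higher adjusted over the list alone; adjusted p = 0.2188 with an estimated correlation), and potassium channels in 8 of 21 (9 lower and 1 higher adjusted over the list alone; adjusted p = 0.0058 with an estimated correlation). Of the 10 genes with the largest differences in the PM response, 6 lost their calls without at least 1 single array, namely Saa3, C3ar1, Dnah12, Net1, Chia1 and Gabrp. Saa3 and C3ar1 did so without heart wild-type PBS replicate 1 (-3.46 and -2.48), for example. Of the 10 for the dnCREB effect, 2 did, namely Xist and Car3. The PM count was 129 without that array, 542 without lung wild-type PM replicate 1, and 311 and 379 without lung wild-type PBS replicates 1 and 3. The dnCREB count was 633 without heart dnCREB PBS replicate 3 and 620 without lung dnCREB PBS replicate 1. The tissues appear to have been normalized separately, and both the sex classes and the muscle genes differ between the groups behind these differences.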

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

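The tests of the sex of the animals, of atrial tissue and of muscle-bearing tissue in the lung lists were chosen only after the results were seen.

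Differences between groups under the same contrast were collected for a closer look. In lung, the interaction of genotype and PM called 1 gene, Uty (4.81). Of 100 splits of the arrays 10 called as many, up to 14. Regrouping the labels of the lung arrays breaks up the effects of genotype and of PM as well as their interaction. These splits therefore do not test the interaction alone, and they leave chance open for that count. The Y-linked Uty was high only in the wild-type PBS lungs, whose arrays all had high Eif2s3y, so its value does not show a genotype difference in the PM response. The PM response differed between heart and lung in 204 genes. The largest were Sema3c (2.02), Dnah12 (1.37), Net1 (1.32), Chia1 (1.32) and Gabrp (1.28), which were higher in heart relative to lung, and Saa3 (-3.58), Mmp12 (-3.04), Esm1 (-2.91), Timp1 (-2.83) and C3ar1 (-2.59), which were lower. Of the 204 genes, 113 passed the level filter in lung only, Dnah12, Chia1, Gabrp, Saa3 and Mmp12 among them, so their values restate the change in lung. Dnah12, Net1, Chia1, Gabrp, Saa3 and C3ar1 lost their calls without at least 1 single array. For this count 2 of 100 splits, the real one among them, reached the real value, so the share of splits excludes chance for the count of 204 at 0.05. Yet the highest other split called 664, several times the real count, and what set that split apart was not tested. Regrouping the labels also breaks up the PM response within lung, which called 784 genes averaged over the genotypes, against 0 in heart. The splits therefore do not show whether a difference between the tissues contributes to the count of 204.

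The effect of dnCREB under PBS differed between the tissues in 987 genes, and 1 of 100 splits, the real one, gave as many, with 891 in the highest other. The share of splits excludes chance for the count of 987. Regrouped within a single tissue, the same comparison called at most 0 genes in heart and 1 in lung outside the real grouping (10 splits each). Whether the split with 891 genes kept the real heart labels was not tested. The splits therefore do not show whether the lung labels, and so a difference between the tissues, contribute to the count. Eif2s3y (14.24), Uty (11.19), Kdm5d (9.73), Ltbp2 (7.66) and Timp1 (7.05) were higher in heart relative to lung, and Xist (-13.41), Car3 (-7.32), Ces1d (-6.61), Mylk4 (-5.65) and Tbc1d10c (-4.86) were lower. Xist and Car3 lost their calls without several single arrays. The lymphocyte list (median of -0.82) and the potassium and pacemaker channel list (median of -0.59) also differed between the tissues, with an estimated correlation as well, but only 3 of 21 lymphocyte markers passed the level filter in both tissues, so the former value is mostly that of lung.

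The dnCREB hearts differed from wild-type hearts in 1869 genes under PBS and 2042 under PM, and 10 splits of 6 arrays are too few for a share under 0.05, with 0 in the highest other split in both. The sex of the animals cannot be told apart from genotype under PBS. In the single dnCREB PM heart with high Xist, the genes called under PBS had a median change of 0.91 in the called direction against wild-type PM hearts, beside 0.87 and 0.80 in the dnCREB PM hearts with high Eif2s3y, but that is 1 array. The median of -1.20 of the 3 measured atrial genes (of 6 named) rests on Kcnj3 and Kcnj5, whose falls had been seen before, and other atrial genes, Myl4 (3.25) and Nppa (2.10), rose, so more atrial tissue in the dnCREB samples is argued against only by the abundant atrial genes Myl7 and Sln, which reached at most 2.44 and 1.93 in any heart array, against means of 11.55 and 10.19 in lung. An effect of the transgene on the failing heart stays open as a biological explanation.

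Averaged over the genotypes, interferon, macrophage and lymphocyte lists were higher in PM lungs by camera, each with adjusted p = 0.5047 with an estimated correlation. In dnCREB lung alone, lymphocyte markers had 12 of 20 members above 0 and a camera adjusted p = 0.3132. Muscle-bearing tissue in some samples is argued against as the whole cause, because in dnCREB lungs, where the muscle genes lean towards PBS, the mean score of the 3 lists was still 0.57 higher with PM. Across all 12 arrays the lowest PM value of that mean was 0.13 and the highest PBS value -0.25. The lymphocyte score alone overlapped, at 0.25 in dnCREB PBS replicate 1, 0.24 in dnCREB PM replicate 3 and 0.08 in wild-type PM replicate 3. With the sex-chromosome class as a term the PM coefficient was 1.12 (0.69 to 1.55, 95% interval). It rests on wild-type PM replicate 2 (mean score of 0.96), the only PM array with high Eif2s3y, and dnCREB PBS replicate 2 (-0.42), the only PBS array with high Xist. No other arrays separate PM from the class within a genotype, so the sex of the animals stays open. A response to PM in lung stays as a hypothesis, found and tested on the same arrays.

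Skeletal muscle genes were high in 5 lung arrays. A list of stratified squamous epithelium genes was 1.84 higher in those 5 than in the other 7, with 9 of 16 named genes measured and 5 of them separating the arrays, among them Krt5 (7.45 against 3.32). Only Krt5 and Krt15 did so with all 5 arrays above the level of 4. Krt14 (lowest of 2.00 against a highest of 1.99) and Tgm3 (2.02 against 1.93) separated them at background, and Pkp1 had a lowest value of 3.40. Muscle of the chest wall or diaphragm alone is argued against by that value of 1.84, as it carries no such epithelium. Tissue with squamous epithelium and muscle, such as oesophagus, is a candidate source, as a hypothesis. No biological explanation was tested.

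Splits of the arrays were also counted for the other results. For PM in lung averaged over the genotypes, 1 of 100 splits, the real one, reached 784 genes, with 64 in the highest other, so chance is excluded. For PM in wild-type lung (277 genes, with 1 in the highest other), PM in dnCREB lung (1 and 1, reached by 4 splits), and dnCREB lung under PBS (3 and 1), the 10 splits are too few. They are too few as well for PM in wild-type heart (1 and 0). Where the real count was 0, every split reaches it by construction, so the splits say nothing on chance. This holds for dnCREB lung under PM (2 in the highest other of 10 splits), PM in dnCREB heart (6 in the highest other of 10 splits), and PM averaged over the genotypes in heart and the heart interaction (5 and 47 in the highest other of 100 splits).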

How the results depend on the processing

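The settings chosen only after the results were seen are the sex-chromosome class as a covariate, leaving out the lung arrays with high skeletal muscle genes, the muscle class as a covariate and leaving out the 2 least correlated lung arrays. Of 197 counts under another setting, arrays left out aside, 136 stayed within 1.5 times and 61 moved, and the cause was not tested for any of them. Of those 136, 14 were counts with the 1.5-fold filter, which only removes genes from the main calls. For named genes, planned settings gave 2308 of 2697 values on the same side of the threshold, 357 that lost and 32 that gained a call, and 0 that reversed. The added settings gave 309 of 556 on the same side, 236 lost, 8 gained and 3 reversed. The reversed values, with the sex class as a covariate, were Xist in dnCREB hearts under PBS (1.03), and Kdm5d (-0.01) and Xist (0.28) in the tissue difference of the dnCREB effect. The class is defined by Xist and the Y-linked Eif2s3y. As a covariate it takes up the difference in Xist and in Y-linked genes such as Kdm5d by construction, so these reversals carry no further meaning. Of 108 list calls by camera, 4 held with an estimated correlation. fry, a separate test, called 45 lists, not all of them among the 108.

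With all probe sets, the counts were 533 for PM in wild-type lung, 223 in dnCREB lung and 2243 averaged, 9 for dnCREB lung under PBS, 4 for the lung interaction, 2 for PM in wild-type heart, 2826 for dnCREB heart under PBS, and 721 and 1598 for the tissue differences of the PM response and of the dnCREB effect. With no filter they were 85 for PM in wild-type lung, 0 in dnCREB lung, 507 averaged and 0 in wild-type heart. With the stricter filter they were 0 for PM in dnCREB lung and 1 for dnCREB lung under PBS. Quantile normalization gave 404 for the tissue difference of the PM response. Centred arrays, a variance trend and the replicate block each gave 0 for PM in dnCREB lung, and the block gave 0 for PM in wild-type heart. With only the groups compared the counts were 24 for PM in wild-type lung, 0 in wild-type heart and 1168 for dnCREB heart under PM. With all 24 arrays they were 1694, 53 and 2016 for PM in wild-type, dnCREB and averaged lung, 58 for dnCREB lung under PBS, 15 for the lung interaction, and 0 and 3 for PM in wild-type and dnCREB heart. Array weights gave 738, 1772 and 3031 for PM in wild-type, dnCREB and averaged lung, 172 for dnCREB lung under PBS, 2 for the lung interaction, and 1144 and 2444 for the tissue differences.

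With the sex class, the counts were 2080 and 2 for PM in wild-type and dnCREB lung, 0 for dnCREB lung under PBS, 2 for the lung interaction, 4 and 2 for PM in dnCREB and averaged heart, 337 and 942 for dnCREB heart under PBS and PM, 3 for the heart interaction, and 560 and 185 for the tissue differences. Of the 1869 genes called for dnCREB heart under PBS, 1865 kept their sign with it. Without the arrays with high muscle genes, wild-type PM replicate 3 and dnCREB PBS replicate 2 were the only lung arrays of their groups. The spread then came from the groups with more arrays, so no counts are given for PM in wild-type, dnCREB and averaged lung. The tissue difference of the dnCREB effect gave 282, which also rests on dnCREB PBS replicate 2 alone and cannot test that difference. With the muscle class as a covariate the counts were 11 and 0 for PM in wild-type and dnCREB lung, 1 for dnCREB lung under PBS and 634 for the tissue difference of the dnCREB effect. Without the 2 least correlated arrays they were 27, 0 and 1 for PM in wild-type lung, PM in dnCREB lung and dnCREB lung under PBS.

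Leaving out each array gave 34 to 622 genes for PM in wild-type lung, 0 to 1 in dnCREB lung and 155 to 1324 averaged, 0 to 5 for dnCREB lung under PBS, 0 to 0 under PM and 0 to 3 for the lung interaction. In heart it gave 0 to 3, 0 to 5 and 0 to 2 for PM in wild type, dnCREB and averaged, 1091 to 1678 and 1382 to 2137 for dnCREB under PBS and PM, and 0 to 3 for the interaction. The tissue differences ranged from 129 to 542 for the PM response and from 620 to 1108 for the dnCREB effect. Uty, Calcb and Tdgf1 had no value in lung without a wild-type PBS array, since too few arrays then exceeded the level of 4. Replicate numbers did not pair the arrays: residuals of arrays with the same number correlated with a median r of -0.08 in lung and 0.03 in heart. With the number as a block, 186 genes were called for PM in wild-type lung, 637 averaged, and 1734 and 1889 for dnCREB heart under PBS and PM. Genes under a log2 value of 4 in most arrays were not tested, so changes near background are not seen.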

Other observations

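The test of lung samples against heart samples by sex-chromosome class was chosen only after the values were seen.

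The dnCREB heart under PBS showed further single members of lists that did not move as a whole, each the only or nearly the only member called. The alarmin Il33 rose by 2.65 (of 12 chemokines and cytokines; 1 adjusted over the list alone) and the macrophage growth factor receptor Csf1r by 1.03 (of 14 macrophage markers; 0 adjusted over the list alone). The extracellular superoxide dismutase Sod3 rose by 1.57 and the mitochondrial one, Sod2, fell (-0.52), of 15 oxidative stress genes (1 and 1 adjusted over the list alone). The clock-controlled factor Hlf fell (-2.42, of 15 circadian genes; 1 adjusted over the list alone), as did the lipid droplet protein Plin4 (-1.24, of 6 adipocyte genes; 1 higher and 3 lower adjusted over the list alone), while the transferrin receptor Tfrc (2.20, of 4 erythroid genes; 1 adjusted over the list alone) and Tiparp (0.74, of 5 AhR genes; 1 adjusted over the list alone) rose. Dusp1 was the single member lower of 16 glucocorticoid response genes (1 adjusted over the list alone; 4 with centred arrays and 2 with quantile normalization). Csf1r, Tfrc and Tiparp lost their calls under both of these settings, and with the sex class Il33 (2.41), Csf1r (1.27), Sod3 (1.49), Sod2 (-0.73), Hlf (-1.49), Plin4 (-1.89), Tfrc (1.53) and Tiparp (0.54) lost theirs, while 3 chemokines and cytokines were lower with centred arrays.

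Cell-type and stress lists in the same hearts were mixed. Of 17 cardiomyocyte and atrial markers, Dkk3 (at least 18.9-fold), the natriuretic peptide Nppa (2.10) and the atrial light chain Myl4 (3.25) rose and Ryr2 fell (3 and 3 adjusted over the list alone; 3 and 5 with centred arrays, 3 and 1 with quantile normalization). Of 17 endothelial and smooth muscle markers, the pericyte proteoglycan Cspg4 (2.08), Tagln (1.24) and Des (0.72) rose (3 adjusted over the list alone), and of 7 genes of the alveolar and airway list, the factor Etv5 (2.89), the keratin Krt18 (at least 12.5-fold) and Pdpn (1.89) rose and Hopx (-2.00), a cofactor also found in heart muscle, fell (3 and 1 adjusted over the list alone). In glycolysis, Pfkp (1.41) and Pgam1 (0.61) rose and the insulin-responsive glucose transporter Slc2a4 (-0.96) and Pfkm (-0.50) fell (4 and 4 adjusted over the list alone; 1 and 5 with centred arrays). Among 20 heat shock and unfolded protein genes, Pdia4 (0.93), Asns (1.65) and Ddit3 (0.72) rose and Herpud1 (-1.29) fell (3 and 1 adjusted over the list alone), and Ddit3 lost its call under centred arrays or quantile normalization. Acta1 was the single member called of 5 skeletal muscle genes (1 adjusted over the list alone; 0 with centred arrays). limma called 0 members of the neutrophil (3 measured), lymphocyte (4), mesothelial and lymphoid tissue (4) and cell cycle (10) lists in this comparison, where 3299 genes had an unadjusted p under 0.05. With centred arrays 1 lymphocyte and 2 mesothelial and lymphoid tissue genes were lower, and with the sex class 1 cell cycle gene was higher. With the sex class Dkk3, Slc2a4, Etv5 and Hopx kept their calls, and Nppa (2.14), Myl4 (5.94), Ryr2 (-1.31), Cspg4 (2.06), Tagln (1.12), Des (0.41), Krt18 (4.36), Pdpn (1.84), Pfkp (1.42), Pgam1 (0.83), Pfkm (-0.73), Pdia4 (1.12), Asns (0.73), Ddit3 (0.19), Herpud1 (-1.42) and Acta1 (1.77) lost theirs.

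In lung averaged over the genotypes, the haem oxygenase Hmox1 rose by 1.2 and the glutathione transferase Gstm1 fell (-0.79), of 18 oxidative stress genes (3 and 1 adjusted over the list alone). The coagulation genes F10 (1.74), Procr (0.73) and Plat (0.82) rose, of 18 (4 and 1 adjusted over the list alone).

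The sex-chromosome class was compared between lung and heart arrays of the same group and number. As labelled, 3 of 12 pairs were of the same class. With the lung genotypes exchanged, 9 of 12 were, a count that 2 of the 24 ways to match the groups reach. Whether a lung and a heart of the same number came from the same animal is not stated, so these counts are given as values.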
